A study of Homo sapiens with 120 samples.

How the data were processed

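Polyadenylated RNA of 3 cell lines derived from HEK-293 was profiled by 3′ mRNA-seq (Lexogen QuantSeq, forward kit, 500 ng of total RNA per library, per the labels' protocols). Sampling covered transfected and mock cultures at 0, 4, 24, 48 and 72 h, and the series' design text states 4 biological replicates per condition. The titles hold a number, 1 to 4 in the transfected arm and 5 to 8 in the mock arm of each line, here called the culture number. The labels do not say whether it marks the same culture at each time.

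The deposited table holds CPM (counts per 1000000 assigned reads) for each gene and library, computed by the authors. The submitters' processing notes name STAR 2.7, HTSeq 0.12 and the genome build GRCh38. The annotation version, trimming, strand setting and the handling of reads that map to several places are not given in the sources used here. Genes with near-identical copies, such as histone genes, metallothioneins and tubulin genes, and genes that overlap an antisense gene are therefore uncertain. The reads start at transcript 3′ ends, so a change in the choice of polyadenylation site can appear as a change in level. All CPM values came from whole reads: in each library 100% of the values were whole multiples of the value of 1 read, at a tolerance of 0.01 reads, which returned the reads per gene and the library totals. Of the 120 samples, 1 had an empty column (cell line 3, mock replicate 7, 72 h) and was left out. No pair of libraries in a group agreed within sampling noise (chi-square per gene at least 1.83), so none was counted as a duplicate. Totals ran from 4923083 to 10614138 reads. The kit's reads were counted without use of molecular identifiers as far as the sources say, so that intervals and detection floors (3 reads, 0.28 to 0.61 CPM) cover counting error only.

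Groups were taken from the labels. Which comparisons, gene lists and named genes to report, and most alternatives, were fixed before the data were examined, for a table of raw counts and edgeR's quasi-likelihood test with TMM scaling. As the table holds CPM, the main test was instead limma 3.58.1 with a mean-variance trend on log2(CPM + 0.5), for host genes with at least 1 CPM in at least 4 libraries (16099 of 38498). Fold changes on this scale understate the change of low genes. A single model with 30 groups of all 119 libraries was fitted, and Benjamini-Hochberg adjustment was made within each comparison at a threshold of 0.05. The comparisons were transfected against mock in each line at each time, the difference of that response among the 3 lines (F test), the lines against each other in mock cultures at 0 h, and mock cultures at 72 h against 0 h. The count test (edgeR 4.0.16 with TMM) was run on the recovered reads as an added alternative. It called 376, 0, 480, 5870 and 2192 genes in cell line 1 at 0, 4, 24, 48 and 72 h, 0, 6, 567, 653 and 637 in cell line 2, and 0, 9, 1449, 5560 and 3084 in cell line 3. For the difference among lines it called 0, 49, 4142 and 944 genes from 4 to 72 h. For the pairs of lines it called 8513, 7817 and 9291, and for mock 72 h against 0 h 7185, 6483 and 5072.

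The 4 AAV entries of the table were kept out of the host gene tests. Their levels were compared between groups with two-sided exact permutation tests of log2(CPM + 0.5), adjusted by Benjamini-Hochberg within families of 45 (transfected against mock), 24 (between lines) and 12 (between times) tests.

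Of 40 gene lists, 34 had enough measured members and were tested with camera from limma, with a preset correlation of 0.01. Camera was run on log2(CPM + 0.5), the scale of the main test, and adjusted over lists and the 12 comparisons of 4 to 72 h. Tests of the lists for pairs of lines and for mock 72 h against 0 h were added later. Each call was repeated with an estimated correlation. Counts of stress response genes that differ between lines at other times and in the arm to be transfected, from the same model, were added after the values were seen. Counts of members higher or lower use the adjustment over all genes, and counts adjusted over the list alone are given beside them where they differ.

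Named genes followed a rule. Ranked genes had to be called, have a mean of at least 5 CPM in the higher group and show no overlap between the compared libraries. For the response shared by the 3 lines, the genes with the largest value of the smallest absolute fold change were taken, 8 in each direction. For each line the largest changes in each direction were taken, 6 at 24 and 72 h and 3 at 4 and 48 h, and at 0 h the 3 genes with the smallest p. For the difference among lines the 8 genes with the largest range were taken, and for pairs of lines and mock cultures over time the 5 largest in each direction. Up to 4 members of a gene list were taken by smallest p, as was each measured interferon gene and coagulation factor gene of the lists. Where fewer are named, they are the top of that order. Other genes named (IFIT2 and IFIT3 at 24 h, SLC7A11, CHAC1, DDIT4 and GDF15 over time, F9) and the choice of genes for the course over time came after their values were seen.

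Some genes are not reported here. Positions were taken from GENCODE release 29 (GRCh38) by gene symbol. The fold change of a gene at 0 CPM in a group was given as a lower bound against 3 reads in a library.

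The model was tested on simulated reads for 16099 genes, 200 of them changed by 1.5, 2 or 4-fold. For the response of cell line 1 at 24 h, 55.2, 83.6 and 100% of the changed genes were recovered at these folds, and 7.6% of calls were false. The figures were 44.8, 80.6 and 95.5% with 11.4% false for cell line 3 at 72 h, and 28.4, 71.6 and 98.5% with 7% false for the difference among lines at 24 h. They were 50.7, 76.1 and 90.9% with 7.1% false for cell lines 1 and 2 in mock cultures. For mock 72 h against 0 h in cell line 1 they were 55.2, 82.1 and 95.5% with 11.9% false. Each of these false shares lay above 0.05, the adjusted p threshold of the main test. The figures hold for simulated reads only. In the data the spread was uneven, with a chi-square per gene of 1.83 to 37.8 between libraries of a group. Whether recovery and false calls were alike in the data was not tested.

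Alternatives fixed beforehand were RLE size factors, no filter on low genes, DESeq2 1.42.0, fits with the compared libraries or the line's libraries alone, subtraction of the difference at 0 h, the transfected-arm cultures at 0 h as reference, leaving out each culture, the culture number as a block, and for gene lists an estimated correlation and fry. Alternatives added after the data were seen were pseudocounts of 0.1 and 2 CPM, TMM scaling of CPM, the count test and leaving out 6 mock libraries that held over 5 CPM of AAV reads. Computations used R 4.3.3 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.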

Results

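Messenger RNA was measured in 3 cell lines derived from HEK-293, a human embryonic kidney line used to make recombinant adeno-associated virus (rAAV), a gene therapy vector. Cultures of each line were either transfected or mock treated and sampled at 0, 4, 24, 48 and 72 h. The labels state 4 biological replicates per condition, so that 120 samples fell into 30 groups of 4. Libraries were made with a 3′ mRNA-seq kit, which reads the ends of polyadenylated transcripts, and 119 of them held values. The column of cell line 3, mock replicate 7, at 72 h was empty, so that group had n = 3. The libraries held 4923083 to 10614138 reads assigned to genes (median 6979694), and 3 reads corresponded to 0.28 to 0.61 CPM (counts per 1000000 assigned reads). Between 16868 and 19963 genes were detected per library. Mitochondrial transcripts took 6.8 to 18% of the reads and the 10 most abundant genes 9.4 to 18.5%. Of 38498 host genes, 16099 were tested. Fold changes below are log2 values on the log2(CPM + 0.5) scale ± SE from limma, levels are means ± SD in CPM, and n = 4 per group unless stated. AAV transcripts were outside the limma model, and the SE of their log2 differences comes from the compared libraries alone.

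The AAV transcripts AAV2gs01 and AAV8_gp2 appeared in transfected cultures of all 3 lines and differed several-fold between lines. The AAV8_gp2 transcript, 1 of 4 AAV entries in the table, stood at 70.6 ± 27.2 CPM in cell line 1, 27.9 ± 8.31 in cell line 2 and 100 ± 41.1 in cell line 3 at 4 h. At 24 h it had reached 6486 ± 1426, 3557 ± 407 and 11159 ± 1953 CPM. At 48 h it stood at 7169 ± 1240, 4634 ± 274 and 15544 ± 2338 CPM, the last being 1.55% of all reads, and at 72 h at 2677 ± 482, 4006 ± 203 and 10375 ± 1360 CPM. The means of the AAV2gs01 transcript had the same order at 48 h, with 4317 ± 1907, 2243 ± 250 and 7112 ± 1293 CPM, and ended at 1134 ± 145, 1938 ± 220 and 4700 ± 936 CPM at 72 h. AAV8_gp2 was lower in cell line 2 than in cell line 3 by a log2 difference of −1.64 ± 0.15, −1.74 ± 0.12 and −1.37 ± 0.10 at 24, 48 and 72 h. Cell line 1 stood above cell line 2 at 24 and 48 h (0.85 ± 0.18 and 0.62 ± 0.13) and below it at 72 h (−0.60 ± 0.13). It was below cell line 3 at each of these times (−0.79 ± 0.20, −1.12 ± 0.16 and −1.96 ± 0.16). Each of these 9 AAV8_gp2 differences had an adjusted p of 0.0403 in a two-sided exact permutation test over 24 line comparisons, and p = 0.0286 is the smallest that 4 against 4 libraries allow. For AAV2gs01, cell line 2 lay below cell line 3 by −1.62, −1.65 and −1.26 with the same adjusted p. Cell line 1 minus cell line 3 did not pass at 24 and 48 h (−0.81 and −0.80, adjusted p = 0.131 each by the exact permutation test) and passed at 72 h (−2.04, adjusted p = 0.0403 by that test). Cell line 1 minus cell line 2 at 24 h, 0.81, did not pass (adjusted p = 0.0722 by the exact permutation test, 0.0403 with RLE or TMM scaling). At 48 h the same difference, 0.85, passed on the CPM scale (0.0403) and not with RLE or TMM scaling (0.0686).

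Mock cultures held group means of 0 to 6.75 CPM of AAV8_gp2 and 0 to 5.06 CPM of AAV2gs01. Transfected and mock libraries were fully separated for both transcripts from 4 to 72 h in cell lines 1 and 2 and from 4 to 48 h in cell line 3 (exact permutation p = 0.0286, adjusted p = 0.0443 over 45 tests). At 72 h in cell line 3 the smallest exact permutation p that 4 against 3 libraries allow is 0.0571 (adjusted p = 0.0779), although all transfected libraries lay above the 3 mock libraries. From 48 to 72 h in cell line 1 AAV8_gp2 went down by −1.42 ± 0.18 and AAV2gs01 by −1.84 ± 0.32 (exact permutation p = 0.0286 each). None of the 12 comparisons between times passed adjustment (lowest adjusted p = 0.0571, exact permutation test). AAV2gs01 made up 29.3 to 36.4% of the AAV2gs01 and AAV8_gp2 reads in the transfected groups. AAV5gs01 was present in all groups, mock included, at 1406 ± 115 to 3890 ± 247 CPM, and AAV8_gp1 was at or near 0. At 0 h AAV8_gp2 was higher in mock than in transfected-arm cultures of cell line 1 (−2.98 ± 0.98) and higher in the transfected arm of cell line 3 (1.62 ± 0.56), at means of 6.75 CPM or less (adjusted p = 0.0443, exact permutation test).

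**Figure D1:**
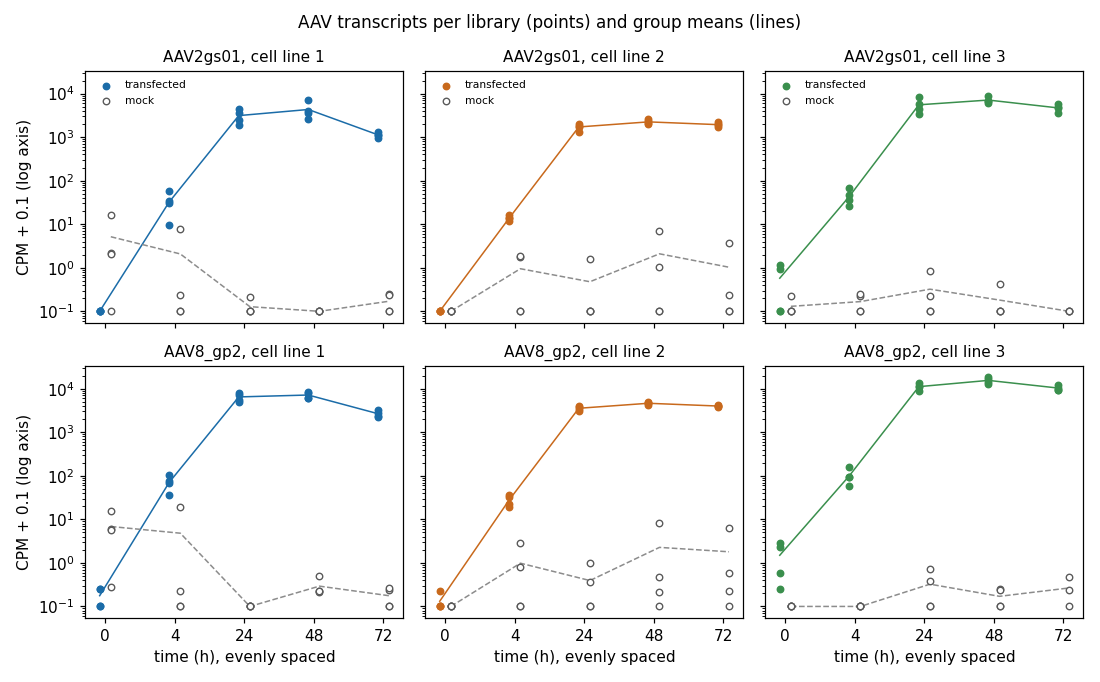
Level of AAV2gs01 and AAV8_gp2 in each library (CPM + 0.1, log axis) against time in hours (evenly spaced), by cell line, with 1 point per library and a line through the group means of transfected (filled) and mock (open) cultures. Transfected cultures of cell line 3 reached a mean of 15544 CPM of AAV8_gp2 at 48 h and those of cell line 2 a mean of 4634 CPM.

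The response of host genes to transfection was compared within each line at each time. Higher and lower here mean transfected against mock cultures of the same time, and not a change from an earlier time. At 24 h CGA, which encodes the common alpha subunit of glycoprotein hormones (chromosome 6, 87085498 to 87095406, GRCh38), was higher in all 3 lines. Its fold changes were 2.39, 2.08 and 2.33 (±0.25 each) in cell lines 1, 2 and 3, and in cell line 1 it stood at 35.4 ± 4.87 CPM against 6.38 ± 1.14 in mock (adjusted p = 5.67e-12). The stress-induced transcription factor ATF3 was higher by 1.71, 1.52 and 1.38 (±0.20) and the eIF2α phosphatase subunit PPP1R15A by 1.11, 1.29 and 1.04 (±0.16). Polyadenylated transcripts of the histone genes H2BC12 (1.11, 1.14 and 2.07 ± 0.13) and H2BC5 (1.13, 1.04 and 2.12) were higher as well. STMND1 (2.54, 1.03 and 1.49 ± 0.19), the protein kinase gene MAK (1.05, 1.21 and 1.04) and the lipid transporter gene MFSD2A (1.03, 1.09 and 1.09) followed. Genes lower in all lines differed less. The DNA glycosylase gene NEIL1 was lower by −0.55, −0.59 and −0.72, PCED1A by −0.68, −0.49 and −0.84, and DAZAP2 by −0.49, −0.55 and −0.76. The zinc transporter gene SLC39A13 was lower by −0.50, −0.58 and −0.47. At this time 104 genes were higher and 16 lower in all 3 lines, where independent lists of these sizes would share 0.51 and 0.04. Without a single culture some of these calls ended, in cell line 1 those of H2BC5 (0.80 without transfected culture 2), DAZAP2 (−0.43 without transfected culture 2 and −0.44 without mock culture 8) and NEIL1 (−0.49 without mock culture 8). In cell line 2 that of PCED1A ended (−0.43 without transfected culture 2 and −0.47 without mock culture 5).

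The genes with the largest differences at 24 h varied with the line. STMN4, a member of the microtubule-binding stathmin family (chromosome 8, 27235323 to 27258420), was higher by 4.07 ± 0.26 in cell line 1 (1.85 and 2.78 in cell lines 2 and 3), where the ankyrin repeat gene ANKRD1 was higher by 2.56 ± 0.31 and VWA1 lower by −1.07 ± 0.27. Cell line 2 showed the largest positive difference in the dynein heavy chain gene DNAH17 (4.39 ± 0.30, with 2.35 and 1.01 in cell lines 1 and 3), followed by INHBA, which encodes the beta A subunit of activins (2.73 ± 0.30), and A1BG was lower by −0.76 ± 0.23. The histone gene H2BC21 was higher by 2.94 ± 0.26 in cell line 3 (0.85 and 1.20 in cell lines 1 and 2), PYCARD-AS1 by 2.29 and the activin subunit gene INHBE by 2.23. In that line the splicing factor gene SF3A2 was lower by −1.52 ± 0.17 and the metallothionein gene MT1F by −1.46 ± 0.23. Genes detected in cell line 2 at 24 h ran from 18251 to 18402 in transfected and from 17107 to 17649 in mock libraries. The numbers of genes higher and lower were 338 and 116 in cell line 1, 605 and 97 in cell line 2, and 650 and 1034 in cell line 3. With RLE or TMM scaling the split was 331 and 252, or 321 and 301, in cell line 2, and 956 and 633, or 832 and 737, in cell line 3. Cell line 2 gave 189 genes with only the compared libraries in the fit and 388 with only its own. With the difference at 0 h subtracted the counts were 757, 140 and 343 in cell lines 1, 2 and 3. Cell line 1 gave 215, 286 and 281 genes without transfected cultures 2 and 3 and mock culture 7 in turn. Cell line 2 gave 404 without mock culture 5 and 438 without transfected culture 2, and cell line 3 gave 1052 without transfected culture 4. The call of H2BC21 in cell line 1 ended without any culture but mock culture 8 (0.72 to 0.94). The call of VWA1 ended without transfected culture 2 or 3 (−0.98 and −0.97), and that of A1BG without any of transfected cultures 1, 2 and 4 and mock cultures 5 and 6 (−0.77 to −0.58).

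Ribosome biogenesis genes were higher at 24 h in the 3 lines, with 8, 6 and 12 of 26 members higher (14, 8 and 15 adjusted over the list alone). RRP12, a factor of ribosomal subunit assembly, was higher by 1.48, 0.99 and 1.0. The list kept its call in each line (adjusted p = 0.000343, 0.0318 and 0.000709 with an estimated correlation). Of 30 genes of the G1/S transition and DNA replication, 11 were higher in cell line 1 (15 adjusted over the list alone, adjusted p = 2.93e-05 with an estimated correlation), such as the clamp loader subunit RFC2 (0.73) and uracil-DNA glycosylase UNG (0.58). In cell line 3, 10 of them were higher (12 higher and 1 lower adjusted over the list alone, adjusted p = 0.0116 with an estimated correlation), with cyclin E1, CCNE1, at 0.97, and in cell line 2, 2 were higher. Of 21 integrated stress response genes, which ATF4 activates, 8, 6 and 5 were higher (12, 10 and 8 adjusted over the list alone), with the amino acid transporter subunit SLC3A2 at 1.45, 1.34 and 1.0. That call was lost otherwise (adjusted p = 0.153, 0.382 and 0.352 with an estimated correlation). Immediate early and MAP kinase response genes were higher in cell lines 2 and 3, 7 and 5 of 26 members. Adjusted over the list alone, 9 were higher in cell line 2, and 11 were higher and 1 lower in cell line 3 (adjusted p = 0.0119 and 0.00418 with an estimated correlation). Replication-dependent histone genes had 4, 3 and 4 of 14 members higher, and 1 lower in cell line 3 (adjusted p = 0.287, 0.224 and 0.121 with an estimated correlation). In cell line 3 the median of this list was −0.25 while its mean, 0.34, and the test pointed up. There 7 of 23 cholesterol synthesis genes were lower (12 adjusted over the list alone), among them INSIG1 (−0.70, not called without transfected culture 4 at −0.64 or mock culture 7 at −0.65) and FDPS (−0.40), and the call was lost otherwise (adjusted p = 0.219 with an estimated correlation). Also lower were 6 of 30 interferon-stimulated genes (1 higher and 8 lower adjusted over the list alone), among them STAT2 (−0.80) and IFITM1 (−0.84), with adjusted p = 0.119 with an estimated correlation. The interferon-induced IFIT2 and IFIT3 were higher in cell line 2 by 2.36 ± 0.36 and 1.28 ± 0.29, and the whole list was not called there (camera adjusted p = 0.239).

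At 4 h the differences were few. ATF3 was higher by 1.54 ± 0.20 in cell line 2, the immediate early transcription factor gene EGR1 (chromosome 5, 138465490 to 138469315) by 1.29 ± 0.27 and the MAP kinase phosphatase DUSP1 by 1.14 ± 0.18, and the kinase gene MAPK3 was lower by −0.53 ± 0.12. Cell line 3 showed ATF3 higher by 1.30 ± 0.20, EGR1 by 1.22 ± 0.27 and GADD45B by 0.87 ± 0.20. Immediate early and MAP kinase response genes made up 6 of the 14 higher genes of cell line 2 and 7 of the 21 of cell line 3 (8 of 26 in each adjusted over the list alone). Among them JUN stood at 0.96 ± 0.13 and 0.77 and JUND at 0.49 ± 0.11 and 0.71 (adjusted p = 0.00148 and 2.93e-05 for the list with an estimated correlation). Cell line 2 had 14 genes higher and 3 lower and cell line 3 had 21 higher and 2 lower, with 6 higher in both. Of the 35 splits of the libraries of cell line 2 into groups of 4, the real one included, 6 gave 17 genes or more, and the highest other count was 1884. In cell line 1 limma called 0 genes, against 1029 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by edgeR. The ribosome biogenesis list was higher as a set in that line (5 members adjusted over the list alone, adjusted p = 0.00511 with an estimated correlation). Its unfolded protein response genes were called lower with the preset correlation (8 members adjusted over the list alone) and not otherwise (adjusted p = 0.226 with an estimated correlation). The count of cell line 2 was 377 without mock culture 7, 180 without mock culture 8 and 6 to 26 without each of the others. The count of cell line 3 was 6 to 26 as single cultures were left out, and 13 with RLE or TMM scaling. With only the compared libraries in the fit the counts of cell lines 2 and 3 were 1 and 0, with the difference at 0 h subtracted those of cell lines 1, 2 and 3 were 100, 5 and 4, and without a filter on low genes 30, 34 and 40. Cell line 2 gave 6 with only its own libraries, and edgeR gave 6 and 9 in cell lines 2 and 3. In cell line 2 the call of EGR1 ended without transfected culture 3 (1.15) or mock culture 6 (1.21), that of JUND without transfected cultures 1, 2 or 3 or mock cultures 5 or 6 (0.43 to 0.52), and that of MAPK3 without transfected cultures 1, 2 or 4 or mock cultures 5 or 6 (−0.55 to −0.44). In cell line 3 the call of EGR1 ended without transfected cultures 2 or 3 or mock cultures 5, 6 or 8 (1.13 to 1.26), and that of GADD45B without any culture but transfected culture 1 and mock culture 6 (0.76 to 0.90).

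At 48 h the differences were far broader in cell lines 1 and 3 than in cell line 2. STMN4 was higher by 5.90, 3.47 and 4.22 (±0.26) in cell lines 1, 2 and 3, and reached 78.93 ± 8.96 CPM against 0.848 ± 0.310 in the mock cultures of cell line 1 (adjusted p = 9.36e-38). TNFRSF12A, a receptor of the TNF family, was higher by 2.81, 2.19 and 2.13 (±0.27), and the neuronal tubulin gene TUBB3 by 1.5, 1.07 and 2.81 (±0.18). CGA (2.59, 1.88 and 2.06), H2BC12 (1.30, 1.15 and 2.41) and the ribosome assembly gene RRP12 (1.58, 0.88 and 1.10) were higher too. TXNIP, whose product binds thioredoxin, was lower by −2.42, −0.80 and −1.12 (±0.23), and TRIM66 by −1.02, −0.83 and −1.19. DCST1-AS1 was lower by −0.79, −0.90 and −1.07 and the transcription factor gene CREB3L4 by −1.01, −0.77 and −0.96. The cystine transporter gene SLC7A11 (chromosome 4, 138164097 to 138242349) was lower by −3.78 ± 0.45 in cell line 1, at 32.86 ± 4.44 CPM against 455.4 ± 50.1 in mock. The glutathione-degrading enzyme gene CHAC1 (−3.47 ± 0.46) and DDIT4, which encodes an mTORC1 inhibitor (−3.14 ± 0.23), were also lower there, while SH2D3C was higher by 3.44 ± 0.28. From 24 to 48 h CHAC1 stood at 5.93 and 6.13 CPM in transfected and at 1.65 and 70.8 in mock cultures, and DDIT4 at 9.35 and 11.2 in transfected and at 9.66 and 97.0 in mock cultures. In cell line 3 the stress cytokine gene GDF15 (−3.93 ± 0.45), PEX5L (−3.38) and the fucosyltransferase gene FUT1 (−3.08) were lower, GDF15 going from 6.61 to 23.3 CPM in transfected and from 5.07 to 326 in mock cultures over these times, and the kisspeptin receptor gene KISS1R was higher by 2.64 ± 0.29. In cell line 2, DNAH17 was higher by 2.75 ± 0.30 and NINJ2-AS1 lower by −0.90. Higher and lower genes numbered 2601 and 3150 in cell line 1, 645 and 206 in cell line 2 (376 and 332 with RLE scaling, 385 and 320 with TMM) and 2781 and 2734 in cell line 3. Shared by the 3 lines were 253 higher and 103 lower genes, where independent lists would share 18 and 6.85. The mock cultures of cell line 2 stood apart in this comparison, cultures 5 and 6 from 7 and 8, with a chi-square per gene of 2.33 and 2.81 within and 8.02 to 14.4 across these pairs. They held 14.1 to 249 CPM of SLC7A11 and 4.3 to 99.1 CPM of CHAC1. The arms of cell line 2 did not overlap in mitochondrial reads (14.9 to 15.6% in mock, 11.2 to 12.7% in transfected libraries), the share of the 10 most abundant genes (15.5 to 16.1% and 12.1 to 13.2%) or genes detected (17209 to 18367 and 18455 to 18891). Assigned reads in cell line 1 ran from 7400398 to 8692815 in mock and from 6254732 to 7375395 in transfected libraries. Counts were 3767 in cell line 1 and 406 in cell line 2 with only the compared libraries in the fit, 511 in cell line 2 with only its own, 419 there without 6 mock libraries with AAV reads, and 116 and 2527 in cell lines 2 and 3 with the difference at 0 h subtracted. The count of cell line 2, 851, was 357, 414, 558, 502 and 494 without mock cultures 5 and 6 and transfected cultures 1, 3 and 4 in turn. There the call of CREB3L4 ended without mock cultures 5 or 6 (−0.61 and −0.59), that of TXNIP without these or transfected cultures 3 or 4 (−0.81 to −0.68), and that of NINJ2-AS1 without mock culture 5 or transfected cultures 1 or 3 (−0.84 to −0.82).

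Integrated stress response genes were lower at 48 h in cell lines 1 and 3, 19 of 21 members in each, and their calls were lost otherwise (adjusted p = 0.068 and 0.183 with an estimated correlation). SESN2 (−2.11) and the serine synthesis gene PSAT1 (−2.35) were among them in cell line 1. Targets of p53 were lower in both lines, 18 of 22 with 1 higher in cell line 1 and 19 of 22 in cell line 3, and kept their calls (adjusted p = 0.00764 and 0.00152 with an estimated correlation). MDM2, the ubiquitin ligase of p53, stood at −0.85 and −1.02, and the apoptosis gene PMAIP1 at −1.34 in cell line 1. Cholesterol synthesis genes were higher, 17 of 23 in cell line 1 (adjusted p = 0.0956 with an estimated correlation) and 18 in cell line 3 (adjusted p = 0.0119 with an estimated correlation), with DHCR7 at 1.18 and 1.54. Heat shock genes were higher, 11 of 16 in each line, with the chaperone gene HSPA8 at 1.67 ± 0.18 in cell line 1 (adjusted p = 0.00675 and 0.0364 with an estimated correlation). Of 18 glycolysis genes, 11 were higher in cell line 1, such as LDHA (1.21) and PKM (1.07), with adjusted p = 0.0488 with an estimated correlation. Of 29 nuclear oxidative phosphorylation genes, 22 were higher there (adjusted p = 0.136 with an estimated correlation). Fatty acid synthesis genes had 6 of 13 members higher and 1 lower in cell line 3, with the desaturase gene SCD at 1.19 and the elongase gene ELOVL6 at 1.07 (adjusted p = 0.0284 with an estimated correlation). Cell line 2 had 7 of 26 ribosome biogenesis genes higher (15 adjusted over the list alone, adjusted p = 0.00914 with an estimated correlation). It also had 7 of 24 proteasome genes higher, such as PSMC3 at 0.46 (11 adjusted over the list alone, adjusted p = 0.0237 with an estimated correlation). Of 30 interferon-stimulated genes 5 were higher there, such as IFIT3 at 1.92 (10 higher and 1 lower adjusted over the list alone, adjusted p = 0.0116 with an estimated correlation). Adjusted over the list alone, the counts in cell lines 1 and 3 were 19 lower integrated stress response genes in cell line 1, 21 lower p53 targets and 19 higher cholesterol genes in cell line 3, and 13 higher and 1 lower heat shock genes and 12 higher and 1 lower glycolysis genes in cell line 1.

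**Figure D2:**
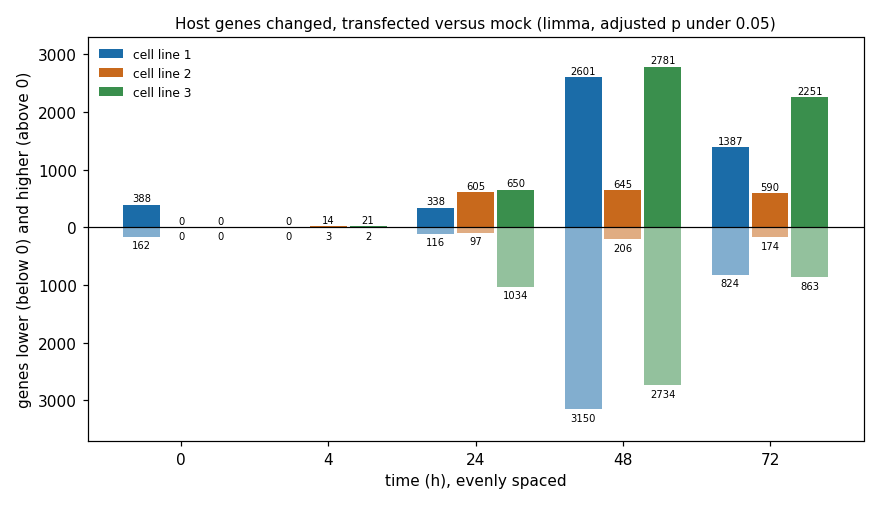
Number of host genes higher (upward bars) and lower (downward bars) in transfected than in mock cultures, by limma at an adjusted p under 0.05, for each cell line at 0, 4, 24, 48 and 72 h. Cell lines 1 and 3 had 5751 and 5515 such genes at 48 h and cell line 2 had 851.

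At 72 h STMN4 was still higher in transfected cultures, by 5.18, 3.64 and 3.92, and CGA by 1.03, 1.02 and 1.31. Also higher in all 3 lines were KIF9 (0.98, 0.88 and 1.04), CCDC173 (1.46, 0.83 and 2.25) and GPATCH4 (0.94, 0.72 and 1.32), and then MNS1 (1.20, 0.71 and 1.28) and the replication origin gene ORC1 (0.86, 0.69 and 0.74). Lower in all 3 lines were the p53 targets TP53INP1 (−0.77, −0.61 and −1.09) and ZMAT3 (−0.56, −0.47 and −1.21) and the neonatal Fc receptor gene FCGRT (−0.61, −0.49 and −0.53). EGR1 was higher by 2.76 ± 0.27 in cell line 1, the natriuretic peptide receptor gene NPR3 by 2.61 and the ETS factor gene ETV5 by 2.31 ± 0.26, and UNC5B-AS1 (−1.51) and INPP5D (−1.31) were lower. Cell line 2 had H2BC12 (2.02 ± 0.13), ETV7 (1.72) and the interferon-induced IFI6 (1.69 ± 0.16) higher, and S100P (−1.76) and the TNF receptor family gene TNFRSF9 (−1.74) lower. Cell line 3 (mock n = 3) had the tubulin gene TUBA4A (2.75) and ETV4 (2.51 ± 0.27) higher, and TNFRSF9 (−2.45), CCDC178 (−2.34) and ELSPBP1 (−2.31) lower. Genes higher and lower numbered 1387 and 824 in cell line 1, 590 and 174 in cell line 2 and 2251 and 863 in cell line 3. With RLE or TMM scaling the split was 403 and 305, or 384 and 333, in cell line 2, and 1703 and 1513, or 1647 and 1589, in cell line 3. All 3 lines shared 172 higher and 25 lower genes, where independent lists would share 7.11 and 0.48. Without transfected culture 4 the count of cell line 2, 764, was 295. It was 162 with only the compared libraries in the fit, 495 with only the line's and 163 with the difference at 0 h subtracted, which gave 1163 in cell line 3. Genes detected in cell line 2 ran from 18565 to 19963 in transfected and from 17614 to 18322 in mock libraries, and the 10 most abundant genes of cell line 1 took 10 to 11.7% and 12.2 to 14.7% of the reads. In cell line 2 the call of TP53INP1 ended without transfected cultures 3 or 4 or mock cultures 5, 6 or 7 (−0.69 to −0.45) and that of FCGRT without transfected cultures 2, 3 or 4 or mock cultures 5 or 6 (−0.52 to −0.39). In cell line 3 the call of FCGRT ended without mock culture 8 (−0.39).

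Ribosome biogenesis genes were higher in the 3 lines at 72 h, 19, 5 and 21 of 26 (22, 8 and 22 adjusted over the list alone). RRP12 stood at 1.51, 0.61 and 1.52 and NOLC1 at 0.66, 0.49 and 0.69 (adjusted p = 2.93e-05, 0.0398 and 0.000406 for the list with an estimated correlation). In cell line 2 the call of RRP12 ended without transfected culture 4 (0.59) or mock culture 7 (0.50) or 8 (0.54). Targets of p53 were lower in cell lines 1 and 3, 14 and 12 of 22 (17 and 15 adjusted over the list alone, adjusted p = 0.00218 and 0.00128 with an estimated correlation), with the cell cycle inhibitor gene CDKN1A at −0.91 and −1.16. In cell line 2, 2 of 22 were lower, the list was not called (camera adjusted p = 0.0799) and CDKN1A stood at −0.29. Interferon-stimulated genes were higher in cell line 2, 11 of 30 (12 adjusted over the list alone, adjusted p = 6.23e-05 with an estimated correlation), with IFIT1 at 1.53 and IFI44L at 1.37. At 24, 48 and 72 h IFIT1 stood at 5.97, 4.69 and 2.34 CPM in transfected and at 3.98, 2.51 and 0.54 CPM in mock cultures of that line. The libraries of that line overlapped at 48 h. At that time IFIT1 was also higher, without overlap, in cell lines 1 (4.13 against 1.71 CPM) and 3 (2.61 against 0.277). At 24 h its means were lower in transfected cultures of these lines (3.43 against 6.66 and 3.15 against 4.23 CPM). In cell line 2, 14 of 23 cholesterol synthesis genes were also higher at 72 h, such as FDFT1 at 0.84 (18 adjusted over the list alone, adjusted p = 0.0259 with an estimated correlation). Of 11 replication-independent histone genes 3 were lower in that line (adjusted p = 0.000406 with an estimated correlation). Immediate early and MAP kinase genes were higher in cell line 3, 14 of 26 with 1 lower (adjusted p = 0.0174 with an estimated correlation). There 3 of 6 immunoproteasome and MHC class I genes were higher, among them the transactivator gene NLRC5 (1.73) and PSMB10 (1.59) (adjusted p = 0.0482 with an estimated correlation). IFNE, the single interferon gene measured, was not called in any line at any time (−0.63 to 0.67, SE 0.31 to 0.34). F8, the gene of coagulation factor VIII, was lower by −0.71 ± 0.16 in cell line 1 at 48 h (15.5 CPM against 25.5 in mock, from 11.7 and 14 at 24 h) and by −0.72 ± 0.16 and −1.04 ± 0.16 in cell line 3 at 24 and 48 h.

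**Figure D3:**
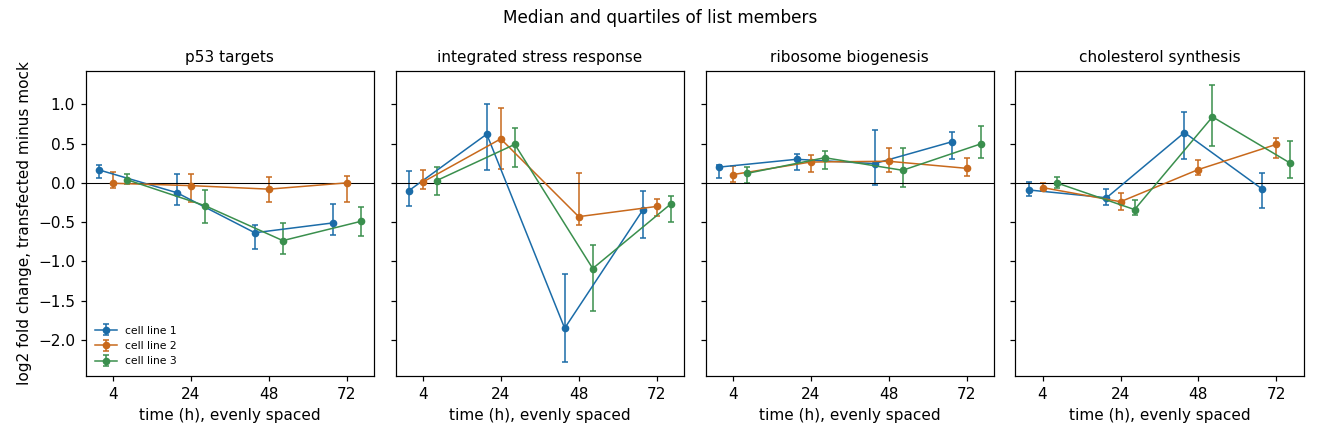
Median log2 fold change, transfected minus mock, of 4 gene lists (p53 targets, integrated stress response, ribosome biogenesis and cholesterol synthesis) at 4, 24, 48 and 72 h in each cell line, with bars from the lower to the upper quartile of the members. The median of the integrated stress response list in cell line 1 was −1.85 at 48 h.

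At 0 h the arms were compared as a background. The transcription factor genes MAF (0.87 ± 0.14) and DACH1 (0.69 ± 0.11) and KANSL1L (1.0 ± 0.17) were higher in the arm of cell line 1 to be transfected, and 388 genes were higher and 162 lower (213 and 323 with RLE scaling, 191 and 337 with TMM). That count was 56 without transfected culture 3, 73 without culture 2, 133 without mock culture 5, 150 without mock culture 7 and 1041 without transfected culture 4. It was 36 without the 3 mock libraries of that group that held over 5 CPM of AAV reads, 0 with only the compared libraries in the fit and 240 with only the line's. Of the 35 splits of these libraries, the real one included, 4 gave 550 genes or more. Libraries of the arm to be transfected held more reads than the mock libraries (6498499 to 7216985 against 5504214 to 6256954) and more detected genes (17929 to 18509 against 17278 to 17607). In cell lines 2 and 3 limma called 0 genes, against 426 and 490 at an unadjusted p under 0.05, 0 and 1 by DESeq2 and 0 by edgeR.

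Whether the response differed among the lines was tested directly. At 24 h the widest differences among genes with at least 5 CPM in a group and libraries apart in at least 1 line were in DNAH17 (2.35, 4.39 and 1.01 in cell lines 1, 2 and 3), STMN4 (4.07, 1.85 and 2.78), H2BC21 (0.85, 1.20 and 2.94) and the matrix protein gene THBS2 (0.59, 1.74 and −0.32), while IFIT2, below that level with a highest mean of 3.98 CPM, had a range of 2.65. At 72 h the widest was in EGR1, which was higher by 2.76 and 2.09 in cell lines 1 and 3 and stood at −0.33 in cell line 2 (adjusted p = 7.1e-09, limma F test). The ETS factor genes ETV5 (2.31, −0.31 and 1.44) and ETV4 (2.08, 0.09 and 2.51) and NPR3 (2.61, 0.39 and 1.33) followed. MAFF (1.87, −0.07 and 1.87) and the complexin gene CPLX1 (1.56, −0.41 and 0.21) differed as well, and ELSPBP1 stood at −0.63, −0.29 and −2.31. The F test with 2 degrees of freedom called 1 gene at 4 h, 63 at 24 h, 4345 at 48 h and 1003 at 72 h. Of 100 splits with reassigned arms, the real one included, 16, 6, 2 and 7 gave as many. At 24, 48 and 72 h these splits do not test chance, since reversing the arms of 1 line turns a shared response into a difference among lines. At 48 h the mock cultures of cell line 2 stood apart (14.1 to 249 CPM of SLC7A11), and the count may partly reflect that spread. At 24 h DESeq2 called 406 genes and the fit of the compared libraries alone 137, and with the difference at 0 h subtracted the counts were 10, 25 and 2669 at 4, 24 and 48 h. Across genes, which are not independent replicates, the responses of cell lines 1 and 3 correlated with r = 0.48, 0.53 and 0.48 at 24, 48 and 72 h. Those of cell lines 1 and 2 correlated with 0.39, 0.29 and 0.22, and those of cell lines 2 and 3 with 0.35, 0.33 and 0.41.

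The lines were far apart in mock cultures at 0 h. SOX11, a transcription factor gene of neural progenitors (chromosome 2, 5692667 to 5701385), stood at 2256 ± 516 CPM in mock cultures of cell line 1 at 0 h, at 1395 ± 122 in cell line 2 and at 0.254 ± 0.238 in cell line 3. The fitted differences from cell line 3 were 11.58 ± 0.29 and 10.91 ± 0.29. The orphan receptor gene GPR50 was higher in cell line 1 than in cell line 2 by 9.52 ± 0.30 and than in cell line 3 by 9.22, and the kinase gene PRKX than in cell line 2 by 6.49 ± 0.12. FAM111B was lower in cell line 1 than in cell line 2 by −8.27 ± 0.20 and higher in cell line 2 than in cell line 3 by 8.57, and the neurofilament gene NEFM was lower in cell line 1 than in cell line 3 by −8.50 ± 0.21. TCEAL7 (7.63) and the retrotransposon-derived PEG10 (7.56) were higher in cell line 1 than in cell line 3. TSTD1 (7.87) and PEG10 (7.49) were higher in cell line 2 than in cell line 3, and the neuropeptide gene CALCB was lower (−7.39 ± 0.34). The crystallin gene CRYGD was at 0 in all 4 libraries of cell line 2 and at least 66.4-fold higher in cell line 1, set against 3 reads in a library. The protocadherin gene PCDH11X was at 0 in cell line 1 and at least 113-fold higher in cell line 3. Fitted folds of other genes under 1 CPM in a group depended on the pseudocount and are not bounds.

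In these 0 h libraries all 19 unfolded protein response genes were higher in cell line 1 than in cell line 2, with the chaperone gene HSPA5 at 3.63 ± 0.26 (3257 ± 457 against 264.6 ± 47.0 CPM) and HERPUD1 at 4.27 ± 0.30. The list lost its call otherwise (camera adjusted p = 4.38e-12, adjusted p = 0.11 with an estimated correlation). At 4, 24, 48 and 72 h 13, 2, 8 and 17 of them were higher and 2, 3, 2 and 0 lower, and in the arm to be transfected 18 were higher at 0 h. HSPA5 in mock cultures of cell line 1 stood at 526 ± 38.4 CPM at 4 h and 298 ± 45.0 at 24 h, against 306 ± 15.6 and 293 ± 23 in cell line 2, and ran from 365 to 3512 CPM in its cultures to be transfected at 0 h. Integrated stress response genes at 0 h were higher in cell line 1 than in cell line 2, 19 of 21, and lower in cell line 2 than in cell line 3, 20 of 21 with 1 higher (adjusted p = 0.24 and 0.266 with an estimated correlation). For cell line 1 minus cell line 2, 6, 1, 16 and 6 of 21 were higher and 6, 9, 0 and 6 lower at 4, 24, 48 and 72 h, and for cell line 2 minus cell line 3, 5, 2, 1 and 2 were higher and 6, 9, 20 and 6 lower. SLC7A11 stood at 268, 15.9 and 12 CPM in mock cultures of cell line 1 at 0, 4 and 24 h and at 17.6, 20 and 18.2 in cell line 2, and CHAC1 at 54.6, 1.22 and 1.65 against 2.06, 2.71 and 4.2. Heat shock genes at 0 h, 14 of 16, were lower in cell line 1 than in cell line 2, with HSPB1 at −3.07 ± 0.11 (adjusted p = 0.0322 with an estimated correlation). This list and those that follow were compared between lines at 0 h only, so whether their differences held at other times was not tested. Among epithelial markers, KRT19 stood at 48.8 ± 2.29 CPM in cell line 2 and at 0 in cell line 3 (at least 124-fold), and EPCAM was higher in cell line 2 than in cell line 3 by 4.29 ± 0.18. In that pair 8 of 11 markers were higher and 1 lower (adjusted p = 0.00834 with an estimated correlation). Of the 6 immunoproteasome and MHC class I genes, 3 were higher in cell line 1 and 5 in cell line 2 than in cell line 3 (adjusted p = 0.00834 for each with an estimated correlation). Fatty acid synthesis genes, 7 of 13, were higher in cell line 2 than in cell line 3, with FASN at 2.12 ± 0.14 (adjusted p = 0.00834 with an estimated correlation). Higher and lower genes numbered 4356 and 4209 for cell line 1 minus cell line 2, 3512 and 4414 for cell line 1 minus cell line 3, and 4108 and 5000 for cell line 2 minus cell line 3. The mock libraries of cell line 1 at 0 h included 3 with over 5 CPM of AAV reads, and with 1 library left there the first 2 counts were 5689 and 4675 in place of 8565 and 7926.

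Mock cultures changed with time as well. From 0 to 72 h TNFRSF9 rose by 4.05, 5.19 and 5.17 in cell lines 1, 2 and 3, the phosphatase gene INPP5D by 3.80, 3.64 and 3.81, S100P by 3.31, 3.90 and 3.56, DNAH17 by 4.62, 4.67 and 3.24 and GDF15 by 5.96, 8.13 and 3.23. TEX15 (−1.97, −2.01 and −2.07), the kinase gene MAP2K6 (−1.94, −2.33 and −1.93), IGFBP5, which encodes an IGF-binding protein (−3.04, −1.93 and −2.25), and the carbonic anhydrase gene CA12 (−2.08, −1.80 and −1.70) fell. ANKRD1 rose by 6.02 ± 0.31 in cell line 1 and by 3.57 in cell line 3, where TXNIP fell by −3.20. INHBE (5.22), NUPR1 (5.20) and CHAC1 (5.17) rose in cell line 2, where the collagen gene COL2A1 (−2.97) and the sterol regulator gene INSIG1 (−2.57) fell. Targets of p53 rose in all lines, 21, 17 and 14 of 22 (21, 19 and 14 adjusted over the list alone), with CDKN1A at 2.52, 1.55 and 1.56 and ZMAT3 at 2.14, 0.94 and 1.37. That list kept its calls (adjusted p = 4.95e-05, 0.00113 and 8.65e-05 with an estimated correlation). Ribosome biogenesis genes were lower, 20, 11 and 19 of 26 (adjusted p = 0.000431, 0.0999 and 0.00113 with an estimated correlation). All 21 integrated stress response genes rose in cell line 2 (adjusted p = 0.0093 with an estimated correlation). This difference depends on the level at 0 h, which was not alike in the lines. SLC7A11 stood at 17.6 CPM at 0 h and 225 at 72 h in cell line 2. At 0, 4 and 72 h it stood at 268, 15.9 and 470 CPM in cell line 1 and at 321, 19.9 and 358 in cell line 3. CHAC1 had a like course in cell lines 1 and 3. Of 23 cholesterol synthesis genes, 21 fell in cell line 2, such as FDFT1 at −2.03, as did 15 of 16 heat shock genes (adjusted p = 0.000431 and 0.00163 with an estimated correlation). Of 30 ribosomal protein genes, 27 rose in cell line 3 (adjusted p = 0.0121 with an estimated correlation). The genes that rose and fell numbered 4115 and 3279 in cell line 1, 3513 and 2999 in cell line 2 and 1484 and 4107 in cell line 3. With RLE or TMM scaling the split in cell line 3 was 2618 and 2476, or 2567 and 2508, and the median of all genes was −0.16 on the CPM scale and 0 with RLE. Without the 3 mock libraries of cell line 1 that held AAV reads at 0 h, its count was 4026 in place of 7394.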

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

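Tests chosen only after the result was seen were those of the AAV2 share, of a single rate of misassignment and of the AAV level in mock libraries, of the AAV5gs01 ratio, and of culture age, lag and removal of AAV genes at 48 h. The rules by which the correlation test for mislabelled libraries and the culture age test were read were changed after their values were seen.

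AAV reads appeared in 6 mock libraries at over 5 CPM of AAV2gs01 and AAV8_gp2 together, namely cell line 1 at 0 h replicates 5, 7 and 8 (31.6, 7.99 and 7.46 CPM) and at 4 h replicate 5 (26.5 CPM), and cell line 2 at 48 h replicate 6 (15.2 CPM) and at 72 h replicate 8 (9.78 CPM). A single rate of read misassignment in the mock libraries is argued against by their uneven counts, with a variance over mean of 123 in cell line 1 and 50.1 in cell line 2. An exchange of labels with a transfected library of 4 to 72 h is argued against by the level. Of the 6, 0 reached the lowest such library of its line (45.2 and 31.3 CPM). For the libraries at 0 h this does not test an exchange with the other arm at 0 h. In cell line 1 AAV8_gp2 then ran from 0 to 0.154 CPM in the arm to be transfected and from 0.172 to 15.4 in mock libraries. By whole profile 5 of the 6 correlated best with a mock group of their own line, and the other, cell line 1 at 0 h replicate 8, with the transfected-arm group at 0 h, which was sampled at the same time and is no test of a label. A candidate explanation is a small share of material from transfected cultures. The 95% Clopper-Pearson interval of the AAV2gs01 share overlapped the range of transfected libraries (20.6 to 44.9%) in 6 of 6. Shares above that range were 51.1% (43.5 to 58.8%) in cell line 1 at 0 h replicate 5 and 46.2% (35.6 to 56.9%) in cell line 2 at 48 h replicate 6. The intervals are wide, as from 14.6 to 40.3% in replicate 7 at 0 h, so overlap decides little. Read misassignment at rates that differ between libraries would give like shares and is not told apart by this. The step at which such material could have entered was not tested, and no biological explanation was tested.

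AAV5gs01 stood at a mean of 2367 CPM over the mock libraries, a signal in cultures that were not transfected. Transfected plasmids are argued against as its main source, since mock levels were 82 to 93.7% of transfected levels in the 3 lines, taken over 24 to 72 h together. Single times differed more, as in cell line 1 at 48 h (1406 ± 115 CPM in mock, 2110 ± 374 in transfected cultures). A smaller part that depends on transfection is not excluded by this. Reads shared with a host gene may be the source. The highest within-group correlation of any tested host gene with it was r = 0.682 over all libraries. That gene was picked by this value and not by sequence, so it does not decide the matter. The entry's sequence was not used here, so this stays open, as does an integrated sequence in these lines, which was not tested.

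The difference between the arms at 48 h, 5751 genes in cell line 1 and 5515 in cell line 3, was larger than at 24 or 72 h. Depth is argued against, as libraries thinned to 4923083 reads gave 5753 and 5480 genes, and so is the share taken by AAV reads, as CPM without the AAV genes gave 5707 and 5483. A candidate explanation is that transfected cultures lagged behind the change that mock cultures went through from 24 to 48 h. Set against the other line's mock cultures, with no shared libraries, 86.5% of 2870 genes in cell line 1 and 92.2% of 2841 genes in cell line 3 went the opposite way to that mock change. Culture age over 0 to 72 h stays open (r = −0.16 and −0.1 across genes in cell lines 1 and 3 at 48 h). At 24 h that correlation was 0.18 and 0.23, again with no shared libraries, a sign opposite to that of a lag. At 72 h it was −0.42 and −0.51, but there the same mock libraries entered both sides. An effect of transfection itself stays open too, which the design does not separate from a lag.

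Sets of 4 libraries were screened for a library far from the others, for 610 gene and group pairs, of which 36 stood out where chance gives about 1 in 20, or 30.5. Of these, 5 rest on 1 or 2 reads in a library against 0 in the others, where the rule is met by construction and shows nothing, namely the values of 0.112, 0.12, 0.325 and 0.126 CPM of AAV transcripts and 0.318 CPM of S100P below. Among pairs with at least 3 reads in a library 31 of 593 stood out, where chance gives 29.6. Among AAV transcripts in mock cultures, AAV2gs01 stood out in cell line 1 at 0 h (replicate 5, 16.2 CPM), 4 h (replicate 5, 7.77) and 24 h (replicate 7, 0.112), in cell line 2 at 24 h (replicate 5, 1.51), 48 h (replicate 6, 7.02) and 72 h (replicate 8, 3.59), and in cell line 3 at 0 h (replicate 7, 0.12), 24 h (replicate 6, 0.765) and 48 h (replicate 6, 0.325). AAV8_gp2 stood out in cell line 1 at 4 h (replicate 5, 18.7) and 48 h (replicate 8, 0.405), in cell line 2 at 48 h (replicate 6, 8.19) and 72 h (replicate 8, 6.2), and in the transfected arm of cell line 2 at 0 h (replicate 2, 0.126), and AAV5gs01 in mock cultures of cell line 2 at 0 h (replicate 8, 3175). Among host genes in mock cultures of cell line 1, replicate 8 stood out at 0 h in SOX11 (3023 CPM), MAF (35.7) and NEFM (0.829) and at 72 h in IFNE (2.79), and replicate 6 in CGA at 24 h (8.09) and ANKRD1 at 72 h (81.6). In mock cultures of cell line 2 at 0 h, S100P stood out in replicate 7 (0.318). Transfected cultures of cell line 1 had DACH1 at 0 h (replicate 4, 42.2) and STMN4 at 48 h (replicate 1, 65.6). Those of cell line 2 had SLC3A2 at 24 h (replicate 1, 42.4), and at 72 h MAFF (replicate 1, 5.16), FDFT1 (replicate 4, 144) and H2BC12 (replicate 4, 257). Transfected replicate 1 of cell line 3 stood out at 48 h in GDF15 (44.1), FUT1 (6.63) and PEX5L (2.62) and at 72 h in CCDC178 (2.2) and STMN4 (44.1), as did replicate 3 in SNAP25 at 48 h (3.12) and replicate 4 in H2BC21 at 24 h (15.4) and ZMAT3 at 72 h (72.4).

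The response differed among the lines by limma's F test in 1, 63, 4345 and 1003 genes at 4, 24, 48 and 72 h. The following values are the range of the 3 lines' log2 fold changes of named genes that passed this test. At 24 h the range was 3.38 for DNAH17, 2.65 for IFIT2, 2.22 for STMN4, 2.09 for H2BC21, 2.06 for THBS2, 1.75 for EGR1, 1.66 for GLIS1, 1.59 for ETV5, 1.53 for SF3A2, 1.51 for STMND1, 0.97 for CCNE1 and 0.96 for H2BC12. At 48 h it was largest in GDF15 (4.06), FUT1 (3.03), SH2D3C (2.96), SLC7A11 (2.89), PEX5L (2.89), KISS1R (2.49), STMN4 (2.43), DDIT4 (2.18), IFIT3 (2.05) and SNAP25 (2.04). Mock cultures of cell line 2 stood apart at that time, with 14.1 to 249 CPM of SLC7A11 and 4.3 to 49.6 CPM of GDF15. For such genes the range may partly reflect that spread and not a different response to transfection. Ranges from 1 to 2 at 48 h were those of DNAH17 (1.87), PSAT1 (1.79), TUBB3 (1.74), SESN2 (1.66), TXNIP (1.62), HSPA8 (1.38), DHCR7 (1.26), H2BC12 (1.26), SYT1 (1.17) and SCD (1.16). Below 1 were those of PKM (0.99), LDHA (0.91), PMAIP1 (0.91), ELOVL6 (0.74), F8 (0.72), RRP12 (0.70), MDM2 (0.69), PSMC3 (0.55) and UCHL1 (0.40). At 72 h it was 3.09 for EGR1, 2.62 for ETV5, 2.42 for ETV4, 2.22 for NPR3, 2.02 for ELSPBP1, 1.97 for CPLX1, 1.94 for MAFF, 1.93 for IFIT1, 1.91 for PIK3IP1, 1.78 for IFI6, 1.63 for CCDC178, 1.60 for H2BC12, 1.54 for STMN4, 1.53 for PSMB10 and 1.48 for TUBA4A. Smaller ranges at 72 h were 1.42 for CCDC173, 1.31 for INPP5D, 0.90 for RRP12, 0.87 for CDKN1A, 0.80 for FDFT1, 0.74 for ZMAT3, 0.60 for GPATCH4 and 0.57 for MNS1.

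F9, the gene of coagulation factor IX, which lay below the filter on low genes, had 83 reads in 29 of 36 transfected libraries at 24 to 72 h and 5 reads in 4 of 35 mock libraries of these times, with 0.909 ± 0.297 CPM in cell line 3 at 48 h (SD, n = 4) against 0 in its 4 mock libraries.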

How the results depend on the processing

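Alternatives chosen only after the data were seen were both other pseudocounts, TMM scaling, the count test by edgeR and leaving out 6 mock libraries with AAV reads. Of 28874 values of named genes over the alternatives, 26897 kept their direction and side of the threshold, 1969 kept only their direction and 8 reversed. All were genes called in the main test, many of them picked for large changes in these data. Calls could thus be lost and not gained, and few reversals follow from that choice. Of these values, 11604 came from fits without a single culture, which share most of their libraries. The calls were lost most often with the difference at 0 h subtracted (289 of 833) and with only the libraries compared in the fit (222 of 1606), and 850 of 11604 were lost as single cultures were left out. Of 121 gene list calls, 31 were kept with an estimated correlation, 87 with fry and 114 with RLE size factors. Of 449 values of AAV transcripts, 7 moved by more than the spread between replicates, 2 lost and 2 gained their call. Depth limited low genes, since 3 reads stood for 0.28 to 0.61 CPM. The cause of the following changes was not tested, except that fits with fewer libraries estimate the spread from fewer samples.

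Reversed values were those of RPA1 (−0.04), ELOVL6 (−0.12) and LRP2 (−0.10) in cell line 1 at 48 h with the difference at 0 h subtracted. With transfected-arm cultures at 0 h in place of mock cultures, NFKB2 (0.10) and DUSP1 (0.01) reversed in cell line 1 minus cell line 2, and ETV5 (0.11), H1-3 (0.02) and ATP5F1A (−0.01) in cell line 1 minus cell line 3.

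Counts of genes moved by over 1.5 times as follows. Scaling by RLE or TMM gave 13 and 13 genes in cell line 3 at 4 h, and TMM gave 0 for the difference among lines at 4 h, where pseudocounts of 0.1 and 2 CPM gave 3 and 3. Without a filter the counts were 30 in cell line 1 at 4 h, 32 and 34 in cell line 2 at 0 and 4 h, 27 and 40 in cell line 3 at 0 and 4 h, and 14 for the difference among lines at 4 h. With only the libraries compared, they were 0 and 3767 in cell line 1 at 0 and 48 h, 1, 189, 406 and 162 in cell line 2 from 4 to 72 h, 0 in cell line 3 at 4 h, and 0 and 137 for the difference among lines at 4 and 24 h. With only the line's libraries, they were 240 in cell line 1 at 0 h and 6, 388, 511 and 495 in cell line 2 from 4 to 72 h. With the difference at 0 h subtracted, they were 100 and 757 in cell line 1 at 4 and 24 h, 5, 140, 116 and 163 in cell line 2 and 4, 343, 2527 and 1163 in cell line 3 from 4 to 72 h, and 10, 25 and 2669 for the difference among lines at 4, 24 and 48 h. Without the 6 mock libraries, they were 36 in cell line 1 at 0 h, 419 in cell line 2 at 48 h, 0 for the difference among lines at 4 h, 5689 and 4675 for cell line 1 minus cell lines 2 and 3, and 4026 in mock cultures of cell line 1 over time. There a single library at 0 h was assumed to vary like the other groups. The count test by edgeR gave 6 and 9 genes in cell lines 2 and 3 at 4 h and 0 for the difference among lines at 4 h. DESeq2 gave 1 in cell line 1 at 4 h, 1 and 15 in cell line 3 at 0 and 4 h, and 2 and 406 for the difference among lines at 4 and 24 h.

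Numbers of called gene lists at 4, 24, 48 and 72 h, 10, 11, 13 and 8 in cell line 1, 9, 10, 11 and 10 in cell line 2 and 7, 12, 12 and 8 in cell line 3, were 1, 2, 3 and 2, then 1, 2, 3 and 4, then 2, 3, 4 and 4 with an estimated correlation. With fry they were 4, 7 and 21 in cell line 1 at 4, 24 and 48 h, 2 and 16 in cell line 2 at 4 and 72 h, and 3, 20 and 16 in cell line 3 at 4, 48 and 72 h.

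As single cultures were left out, counts ran in cell line 1 from 56 to 1041 at 0 h, 0 to 26 at 4 h, 215 to 530 at 24 h, 4448 to 5830 at 48 h and 1543 to 2177 at 72 h. Cell line 2 ran from 0 to 3, 6 to 377, 404 to 628, 357 to 1160 and 295 to 703, and cell line 3 from 0 to 1, 6 to 26, 1052 to 1397, 4701 to 5395 and 2192 to 3034. The difference among lines ran from 0 to 3, 42 to 82, 3305 to 4864 and 751 to 1061 at 4, 24, 48 and 72 h. The pairs of lines ran from 8033 to 8252, 7294 to 7527 and 8550 to 8775, and mock cultures over time from 6295 to 6421, 5536 to 5688 and 3955 to 5140.

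Culture numbers were not taken to pair the samples, since same-numbered cultures did not all deviate together in any whole comparison and the labels do not say what a shared number marks. They had correlations over 0.1 in 5 of 11 pairs of mock cultures at 0 and 72 h, 6 of 12 between lines at 0 h, and 10 of 24, 2 of 24, 6 of 24 and 2 of 22 between lines at 4, 24, 48 and 72 h. The own number correlated best in 6, 6, 8, 3, 8 and 4 of these pairs, where chance gives 3, 3, 6, 6, 6 and 6. Among mock cultures of cell line 3 at 0 and 72 h it did so in 3 of 3 pairs (r = 0.09, 0.27 and 0.28), and between mock cultures of cell lines 1 and 3 at 4 h all 4 pairs had r over 0.1 (0.14, 0.13, 0.13 and 0.14) and the own number was best in 3, hints from the data and not the design. With the number as a block the difference among lines at 72 h was 445 genes, and no other count moved by over 1.5 times.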

Other observations

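The tests over other splits of the samples were set before their results were seen, except that for cell line 1 at 0 h, and the genes followed over time were chosen after their values were seen.

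Genes of mitosis were lower in transfected cultures of cell line 3 at 24 h, 8 of 30 members (12 adjusted over the list alone, adjusted p = 0.226 with an estimated correlation), among them CDCA3 (−0.70 ± 0.11), the spindle checkpoint kinase gene TTK (−0.45 ± 0.08), the topoisomerase gene TOP2A (−0.43) and the kinesin gene KIF23 (−0.44). Neuronal marker genes were higher at 48 h in cell line 1, 4 of 10 with 1 lower, and in cell line 3, 4 of 10 (the same counts adjusted over the list alone, adjusted p = 0.0974 and 0.0767 with an estimated correlation). TUBB3 was higher by 1.5 and 2.81, the deubiquitinase gene UCHL1 by 0.63 and 0.55 and the synaptic vesicle fusion gene SNAP25 by 2.21 and 0.75, while SYT1 was lower by −0.97 in cell line 1. The call of SNAP25 in cell line 3 ended without transfected cultures 1, 2 or 4 or mock cultures 5, 6 or 8 (0.63 to 0.78).

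Stress genes that were lower in transfected cultures at 48 h stood higher in mock cultures at 48 h than at 24 h, with no overlap between the libraries given here. In mock cultures of cell line 1, SLC7A11 stood at 268 ± 81.7 CPM at 0 h, 15.9 ± 1.26 at 4 h, 12 ± 2.45 at 24 h, 455 ± 50.1 at 48 h and 470 ± 31.1 at 72 h (SD, n = 4). Transfected cultures stood at 36.4 ± 2.0 at 24 h, 32.9 ± 4.44 at 48 h and 286 ± 14.6 at 72 h. CHAC1 had a like course, with 1.65 ± 0.386, 70.8 ± 3.31 and 66.6 ± 7.05 CPM in mock cultures and 5.93 ± 0.759, 6.13 ± 1.76 and 38.2 ± 6.97 in transfected cultures of cell line 1 at 24, 48 and 72 h. GDF15 in cell line 3 went from 5.07 ± 2.15 at 24 h to 326 ± 32.7 at 48 h and 740 ± 24.3 (n = 3) at 72 h in mock cultures, and from 6.61 ± 0.368 to 23.3 ± 14.1 and 445 ± 167 in transfected cultures. The mock cultures of cell line 2 were apart from each other at 48 h, with 14.1 to 249 CPM of SLC7A11 (117 ± 120), and so were the transfected-arm cultures of cell line 1 at 0 h, with 7.62 to 326 CPM of SLC7A11 and 365 to 3512 CPM of HSPA5.

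Called genes were counted again over other splits of the same libraries, all 35 for a pair of groups, and for the difference among lines 100 drawn ones in which the arms were reassigned within each line. Only the real split gave as many genes for cell line 1 at 24 h (454 genes, highest other split 15), 48 h (5751, 2259) and 72 h (2211, 450), and for cell line 2 at 24 h (702, 60), 48 h (851, 79) and 72 h (764, 68). The same holds for cell line 3 at 4 h (23, 2), 24 h (1684, 23), 48 h (5515, 1779) and 72 h (3114, 1890), for the pairs of lines (8565, 7926 and 9108 against 4197, 3213 and 4165) and for mock cultures over time (7394, 6512 and 5591 against 2775, 2245 and 3489). In each of these 1 of 35 splits, the real one, gave as many genes, which is the smallest share that 35 splits allow. For the difference among lines at 48 h 2 of 100 splits, the real one included, gave 4345 genes or more, and the other gave more than the real one (5003). These shares were not adjusted for the number of comparisons, so none of them alone excludes chance. As many genes for the difference among lines came from 6 of 100 splits at 24 h (63, highest other 1050) and 7 of 100 at 72 h (1003, 2220). At 24, 48 and 72 h these splits do not test chance, which stays open there. A split that reverses the arms of 1 line turns a shared response into a difference among lines. Chance cannot be excluded for that difference at 4 h (1 gene, 16 of 100 splits, highest other 1597), nor in cell line 1 at 0 h (550, 4 of 35, 1096) or cell line 2 at 4 h (17, 6 of 35, 1884). With 0 genes in the real split, 35 of 35 splits gave as many in cell line 1 at 4 h (highest other 86) and in cell lines 2 and 3 at 0 h (476 and 3). Splits that called many times the real count, as at 4 h in cell line 2 and for the difference among lines at 4 h, point to a structure of the samples other than the arms. The 1050 genes for the difference among lines at 24 h do not, since reversed arms can give them. At that time other splits within cell lines 1, 2 and 3 gave at most 15, 60 and 23 genes.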
